A study of Mus musculus with 8 samples.

How the data were processed

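Messenger RNA of 8 samples of mouse primary hepatocytes was sequenced by the study's authors, 4 infected with Ad-LacZ and 4 with Ad-Mfn2 and all taken 48 h after infection, per the labels' protocols. Libraries were made with a stranded mRNA kit from 2 ug of total RNA, per the labels. Groups and replicate numbers were taken from the sample titles. The genome build was mm10, per the submitters' processing notes, and reads had been trimmed, per the file headers. The aligner, the counting program, the gene annotation and the use of strand in counting were not given in the sources used here. The deposited table held 23440 named genes with their coordinates and, for each sample, a count, a TPM and a CPM value. Gene counts in the deposited table were whole numbers with no normalization by the authors and were the basis of all tests. The deposited TPM values, made by the authors per the file headers, were scaled to the same sum in each sample and were used for relative transcript lengths. The column headed CPM, per the file headers, was treated as a score because the authors' values were not plain CPM, as they had been divided by an adjusted library size. That library size was 0.994 to 1.00 of the one computed here, so the authors' scaling and the one used here were nearly equal. The authors' own fold changes and p-values were not used here, and results of some genes that the rule for named genes takes are not reported here. No column of sample values was left unmapped, and no gene of the mitochondrial chromosome was analysed here.

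Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were left out by filterByExpr with the group design, 10684 genes, while the 12756 tested held at least 99.9% of the counts of every sample. Library sizes were scaled by TMM. Ad-Mfn2 was compared with Ad-LacZ by the quasi-likelihood F test (robust, two-sided) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate was fitted, since the labels name no batch. Log2 fold changes are Ad-Mfn2 over Ad-LacZ, with the SE taken as the absolute log2 fold change divided by the square root of F, and CPM values use TMM library sizes with their SD over 4 samples. Named genes were, by a fixed rule, Mfn2, the 8 largest changes each way among genes past the threshold with at least 10 CPM, no overlap between groups and no predicted-gene name, up to 4 members of each list by adjusted p and 1 in the other direction, Mfn1, Opa1 and Dnm1l, and the 2 most abundant markers of each cell type.

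For gene groups, 38 lists were written down, and 35 had at least 5 tested members. Each was tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists), with camera using an estimated correlation, and with fry, which asks whether the members move 1 way on balance without comparing them with other genes. The lists, the rule for named genes, the main test and the alternatives of normalization, filter, test and left-out samples were set before the data were examined. Alternatives were DESeq2 1.42.0, its size factors and upper-quartile factors within edgeR, limma-voom, other filters, library sizes without Mfn2 and each sample left out. Added after the data had been seen were a test against 1.2-fold, the removal of each library's trends with transcript length and GC content, thinning to a common depth, and leaving out Ad-LacZ replicates 3 and 4 or 1 and 2, or Ad-Mfn2 replicates 9 and 11 or 10 and 12, and the fusion and fission list without Mfn2. GC content was known for 94.2% of the genes tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

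Depth set the precision: 3 counts, the limit that a count of 0 allows, equal 0.167 to 0.231 CPM in these samples, a limit that covers counting error only. The biological coefficient of variation was 4.56%. Counts of samples of the same group differed by more than sampling noise in every pair (chi-square per degree of freedom 1.80 to 7.43). Within Ad-LacZ the value was 1.90 for replicates 1 and 2 and 2.30 for replicates 3 and 4. Across these pairs it was 4.43 to 7.43. Each was counted as a sample of its own, although such excess noise can be technical and does not show that the samples were independent. On simulated counts with 200 changed genes and 12669 tested, the test of Ad-Mfn2 against Ad-LacZ recovered 36 of 67 genes changed 1.2-fold, 58 of 66 changed 1.5-fold and 65 of 65 changed 2-fold, with 8 false calls among 167 (4.79%). Simulated counts with no change gave 2 genes and 0 of 35 lists. The simulation drew each gene independently and changed a far smaller share of genes than differed in the data. It therefore checks neither the preset correlation of camera nor TMM scaling when most genes differ.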

Results

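Primary hepatocytes, the main functional cells of the liver, of the wild-type mouse strain C57Bl6/J were infected with 1 of 2 adenoviruses, vehicles that bring a chosen gene into cells. Ad-LacZ carried the gene of a bacterial beta-galactosidase and served as the control virus. Ad-Mfn2 carried Mfn2, the gene of mitofusin 2, an outer mitochondrial membrane GTPase that fuses mitochondria and takes part in their contacts with the endoplasmic reticulum. Messenger RNA was sequenced 48 h after infection in 4 samples per group, numbered 1 to 4 for Ad-LacZ and 9 to 12 for Ad-Mfn2. Counts assigned to genes totalled 16196231 to 17938638 per Ad-LacZ sample (mean 17097188 ± 944759, SD, n = 4). In Ad-Mfn2 they totalled 12981894 to 14802934 (mean 14016942 ± 822403, n = 4). Totals were lower in every Ad-Mfn2 sample (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 samples allow). Nothing in the labels says that the samples of a group came from separate animals or cultures, so all p-values measure only the spread between these samples, which can be technical.

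The comparison of Ad-Mfn2 with Ad-LacZ asked which transcripts differed when hepatocytes received the Mfn2 virus in place of the control virus. With Ad-Mfn2, genes of hepatocyte identity, acute phase proteins, drug-metabolising enzymes, bile acid handling and fatty acid oxidation were higher as groups. They included Vtn, which encodes the plasma protein vitronectin (log2 fold change 1.87, SE 0.05), and Acaa1a, which encodes a peroxisomal thiolase of fatty acid oxidation (0.93, SE 0.05). Genes of cell division, of the ATF4-driven amino acid response and of p53 were lower as groups, Ccne1, the gene of the G1/S regulator cyclin E1 (-2.29, SE 0.05), and Mthfd2, a mitochondrial folate-pathway enzyme (-1.61, SE 0.05), among them. Markers of macrophages and of stellate cells were also lower in the same libraries. Of 35 gene lists tested, camera called 9 higher and 7 lower at an adjusted p under 0.05, and 2 of these, the cell cycle and ATF4 lists, were also called with an estimated correlation.

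Mfn2 itself (chromosome 4, 147873595 to 147904819, minus strand, build mm10) was measured at 111 ± 4.43 CPM in Ad-LacZ and 455 ± 8.70 CPM in Ad-Mfn2 (SD, n = 4 each). These values came from 1765 to 2106 counts per Ad-LacZ sample and from 5963 to 6544 per Ad-Mfn2 sample. All 4 Ad-Mfn2 samples lay above all 4 Ad-LacZ samples, a 4.11-fold difference (log2 fold change 2.04, SE 0.04, adjusted p = 1.09e-19). Viral and cellular Mfn2 reads were not separated in this value. The species and length of the viral insert were not given in the sources used here, so how much of the viral transcript it measures is not known. Of 23440 genes in the table, 12756 had enough counts to be tested, and 8167 of these (64.0%) changed at an adjusted p under 0.05. Among them 4083 were higher and 4084 lower with Ad-Mfn2, a balance that scaling to the bulk of genes favours. Most of these differences were small, with a median absolute log2 fold change of 0.37, and 5980 (73.2%) lay under 1.5-fold. A total of 682 genes reached 2-fold, 266 higher and 416 lower, and 1060 did without the filter on low counts. Against a change of 1.2-fold instead of any change, a test added after the data had been seen, 3755 genes passed. The samples of the 2 groups did not overlap for 7196 genes (56.4%, where chance gives 2.86%). The first principal component, holding 72.7% of the variance, separated the groups. Spearman correlations of log2 CPM were 0.996 to 0.998 within groups against 0.978 to 0.980 between them. The 10 most abundant genes held 8.64 to 9.03% of the counts of Ad-LacZ samples and 11.6 to 11.8% of those of Ad-Mfn2 samples. Within Ad-LacZ, replicates 1 and 2 lay on the other side of the second component (6.61% of the variance) from replicates 3 and 4. Their deviations from the group mean also rose with transcript length across genes (Spearman rho 0.422 and 0.391) where those of replicates 3 and 4 fell (-0.498 and -0.268). Within Ad-Mfn2, replicates 9 and 11 lay on the other side of that component from replicates 10 and 12, with smaller trends (0.111 and 0.231 against -0.261 and -0.0659).

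**Figure D1:**
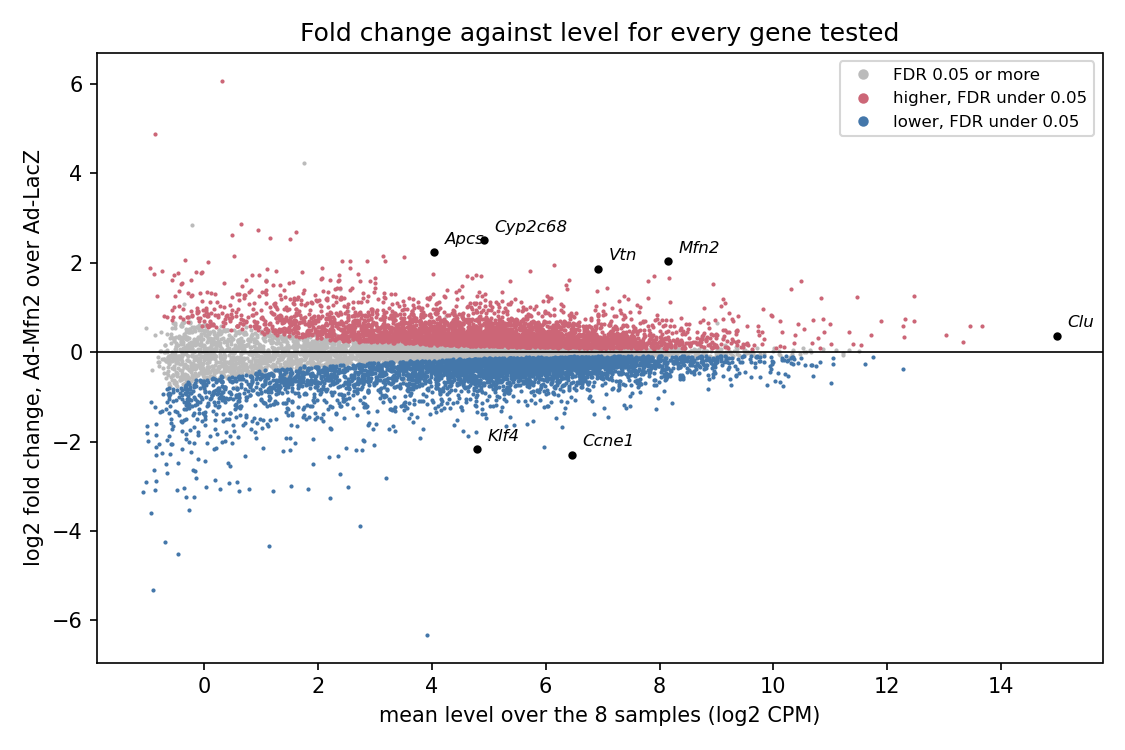
Each point is 1 of the 12756 genes tested, with its mean level over the 8 samples (log2 CPM) on the horizontal axis and its log2 fold change, Ad-Mfn2 over Ad-LacZ, on the vertical axis. Red points were higher and blue points lower at an adjusted p under 0.05, and Mfn2 (2.04) and Ccne1 (-2.29) are among the labelled genes.

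Among genes of at least 10 CPM whose groups did not overlap, the largest rises, above that of Mfn2, were in Cyp2c68 (2.50, SE 0.06), Apcs (2.23, SE 0.08) and Cyp2d10 (2.14, SE 0.10). Cyp2c68 (chromosome 19, 39688836 to 39741101, minus strand) and Cyp2d10 encode cytochrome P450 enzymes, and Apcs encodes serum amyloid P, a secreted pattern-recognition protein. Large rises were also seen in Mfn2, the adhesion receptor Gpr56 (1.95, SE 0.05), Vtn and Pdzk1ip1 (1.75, SE 0.09). In the other direction, Ccne1 (chromosome 7, 38097984 to 38107490, minus strand) was measured at 147 ± 8.95 CPM in Ad-LacZ and 30.0 ± 1.45 CPM in Ad-Mfn2, 4.90-fold lower. The second E-type cyclin Ccne2 (-2.13, SE 0.05) and E2f7 (-1.78, SE 0.08), a transcription factor of the E2F family, were lower with it. Transcription factors Klf4 (-2.16, SE 0.07) and Sox12 (-1.77, SE 0.10), the inducible heat shock protein Hspa1b (-1.92, SE 0.09), the adenylyl cyclase Adcy1 (-1.87, SE 0.07) and the mitochondrial folate enzyme Aldh1l2 (-1.76, SE 0.08) made up the other strong decreases. Adjusted p-values of these genes ran from 1.09e-19 to 2.61e-12. Reads of Hspa1b and Hspa1a, and of members of the Cyp2c and Cyp2d families, can be shared between near-identical copies, so the split between copies is uncertain.

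Genes that mark differentiated hepatocytes rose together. In the hepatocyte identity list, 31 of 35 tested members were higher, 0 lower and 4 not called (31 higher and 1 lower adjusted over the list alone). Their median log2 fold change was 0.72 (camera adjusted p = 5.51e-12, and adjusted p = 0.0726 with an estimated correlation). Foxa2, singled out after its values were seen, was not called (-0.14, SE 0.06, adjusted p = 0.0561) but was called lower under some other settings. These included leaving out Ad-LacZ replicate 4 (-0.16) or Ad-Mfn2 replicate 9 (-0.17) and removing GC trends (-0.22). Vtn, Ahsg (1.52, SE 0.04), which encodes the plasma glycoprotein fetuin-A, and Serpina1a (1.72, SE 0.04) and Serpina1b (1.60, SE 0.04), 2 of the near-identical alpha-1-antitrypsin genes that can share reads, were among the largest. Albumin, the main plasma protein, gained less (Alb, 0.35, SE 0.03) than transferrin (Trf, 0.60, SE 0.03). Acute phase proteins, plasma proteins whose levels change in inflammation, followed: 20 of 24 tested members were higher, 2 lower and 2 not called. Their median was 0.74 (camera adjusted p = 1.73e-07, and adjusted p = 0.109 with an estimated correlation). Apcs led them, with the ferroxidase ceruloplasmin (Cp, 1.26, SE 0.03) and the fibrinogen chains Fgb (1.42, SE 0.04) and Fgg (1.63, SE 0.06), but Il1rn (-1.68, SE 0.05), the gene of the interleukin-1 receptor antagonist, fell. For cytochrome P450 and drug metabolism, 17 of 24 tested members were higher, 4 lower and 3 not called. The median of that list was 0.73 (camera adjusted p = 3.41e-04, and adjusted p = 0.0701 with an estimated correlation). Cyp2c70 (1.08, SE 0.04), Cyp2j5 (1.59, SE 0.05) and Sult1a1 (1.67, SE 0.07) rose beside Cyp2d10, and Por (-0.27, SE 0.04), the gene of the reductase that serves these P450 enzymes, fell. Log2 fold changes of all tested members of that list ran from -2.01 to 2.61. In bile acid synthesis and transport, 14 of 20 tested members were higher, 4 lower and 2 not called, with a median of 0.41 (camera adjusted p = 0.00433, and adjusted p = 0.0726 with an estimated correlation). The acyl-CoA synthetase Slc27a2 (1.14, SE 0.08) and the peroxisomal oxidase Acox2 (0.84, SE 0.06) rose and the canalicular bile salt export pump Abcb11 (-1.22, SE 0.13) fell. In the same libraries the median log2 fold change was -0.42 for macrophage markers and -0.49 for stellate cell markers (-0.28 for those of at least 10 CPM).

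**Figure D2:**
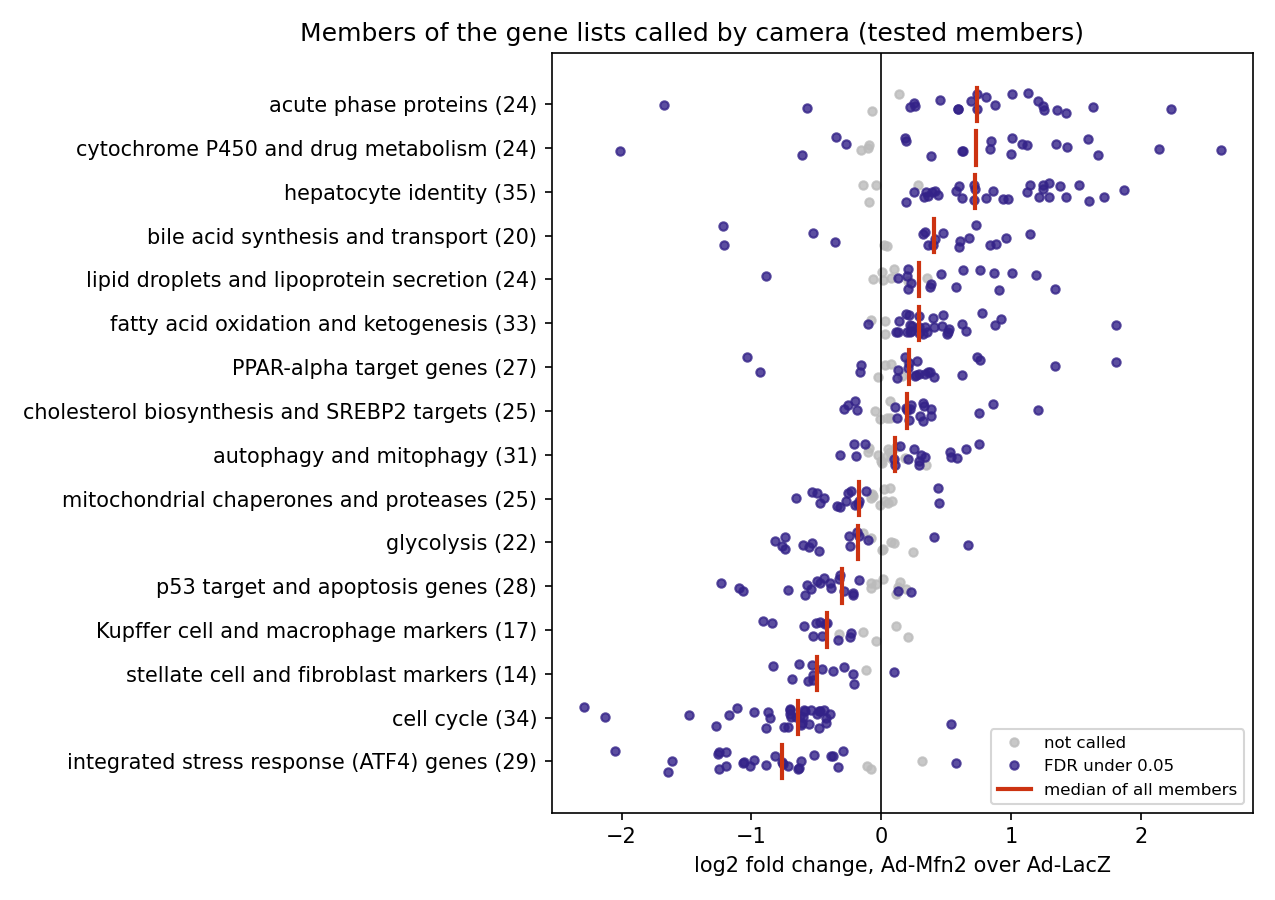
Each point is a tested member of 1 of the 16 gene lists called by camera, with its log2 fold change, Ad-Mfn2 over Ad-LacZ, on the horizontal axis and the number of tested members in parentheses. Dark points passed an adjusted p under 0.05 and red bars mark list medians, which run from -0.76 for the ATF4 genes to 0.74 for acute phase proteins.

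Fatty acid oxidation genes were higher as a group, and those of glycolysis lower. In fatty acid oxidation and ketogenesis, 29 of 33 tested members were higher, 1 lower and 3 not called. The median was 0.29 (camera adjusted p = 1.90e-07, and adjusted p = 0.123 with an estimated correlation). Acaa1a and the dienoyl-CoA reductase Decr1 (0.65, SE 0.04) rose. The carnitine palmitoyltransferases Cpt1a (0.29, SE 0.04) and Cpt2 (0.41, SE 0.05) rose less. The trifunctional protein subunit Hadha (-0.10, SE 0.03) was the single member lower. That call ended without Ad-LacZ replicate 4 (adjusted p = 0.0850) or Ad-Mfn2 replicate 12 (0.0551). Targets of PPAR-alpha, a nuclear receptor for fatty acids, had 18 higher, 4 lower and 5 not called of 27 tested, median 0.21 (camera adjusted p = 0.0103, and adjusted p = 0.0876 with an estimated correlation). There Pdk4 (-0.94, SE 0.08), a kinase that inhibits pyruvate dehydrogenase, fell. Lipid droplet and lipoprotein genes had 16 higher, 1 lower and 7 not called of 24, median 0.29 (camera adjusted p = 0.00183, and adjusted p = 0.133 with an estimated correlation). Among them were the droplet proteins Cideb (1.00, SE 0.07) and Hsd17b13 (0.87, SE 0.05) and the triglyceride lipase Pnpla2 (0.63, SE 0.05), all higher, and its inhibitor G0s2 (-0.89, SE 0.10), lower. Cholesterol synthesis genes had 16 higher, 4 lower and 5 not called of 25, median 0.20 (camera adjusted p = 0.0200, and adjusted p = 0.136 with an estimated correlation). In this list Tm7sf2 (1.21, SE 0.10), Mvk (0.86, SE 0.09) and Hsd17b7 (0.75, SE 0.06) rose. The PPAR-alpha and cholesterol calls ended without Ad-LacZ replicates 1 and 2 (adjusted p = 0.0620 and 0.0516). Glycolysis had 2 higher, 13 lower and 7 not called of 22, median -0.18 (camera adjusted p = 0.0103, and adjusted p = 0.270 with an estimated correlation). Its members Pkm (-0.74, SE 0.04), Aldoa (-0.60, SE 0.04) and Ldha (-0.48, SE 0.03) fell, and Pklr (0.66, SE 0.04), the liver-type pyruvate kinase, rose. Macrophage and stellate cell markers fell in the same libraries (medians -0.42 and -0.49, the latter -0.28 at 10 CPM or more).

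Lipogenesis, gluconeogenesis and insulin signalling were not called as lists by camera among the genes that passed the filter on low counts. De novo lipogenesis and triglyceride synthesis had 12 higher, 4 lower and 9 not called of 25 (camera adjusted p = 0.0956), with the desaturase Scd1 (0.65, SE 0.04) higher and Mid1ip1 (-0.96, SE 0.10), an activator of acetyl-CoA carboxylase, lower. Gluconeogenesis had 8 higher, 3 lower and 6 not called of 17 (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.113), with tyrosine aminotransferase (Tat, 1.71, SE 0.08) higher and aspartate aminotransferase (Got1, -0.69, SE 0.04) lower. Insulin and growth factor signalling had 11 higher, 5 lower and 7 not called of 23 (camera adjusted p = 0.199), with the receptor Egfr (0.69, SE 0.04) higher and the adaptor Grb10 (-0.72, SE 0.07) lower. Without the filter on low counts, lipogenesis (median 0.074 against 0.072, adjusted p = 0.0349) and gluconeogenesis (0.39 against 0.11, adjusted p = 0.0408) were called as higher.

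Of the lists called, cell cycle had the largest share of members lower. Of 34 members tested, 33 were lower and 1 higher. The median log2 fold change was -0.64 (camera adjusted p = 7.51e-14), a call kept with an estimated correlation (adjusted p = 0.00945). Besides the E-type cyclins, the ribonucleotide reductase subunits Rrm1 (-1.27, SE 0.04) and Rrm2 (-1.18, SE 0.04), which make deoxynucleotides, fell. The exception was Ccnd2 (0.54, SE 0.05), a D-type cyclin. Genes of the integrated stress response, most of them targets of the transcription factor ATF4, fell too: 1 of 29 tested members were higher, 25 lower and 3 not called. Their median was -0.76 (camera adjusted p = 1.90e-09), also kept with an estimated correlation (adjusted p = 0.0248). Mthfd2 was measured at 77.2 ± 0.857 CPM in Ad-LacZ and 25.2 ± 1.21 CPM in Ad-Mfn2. The serine and asparagine synthesis genes Phgdh (-1.25, SE 0.05), Psat1 (-1.19, SE 0.04) and Asns (-1.25, SE 0.05) were lower beside it, while the alanine aminotransferase Gpt2 (0.58, SE 0.03) was higher. In the p53 target and apoptosis list, 2 of 28 tested members were higher, 18 lower and 8 not called, with a median of -0.30 (camera adjusted p = 6.99e-04, and adjusted p = 0.0627 with an estimated correlation). The pro-apoptotic Bcl2l11 (-1.23, SE 0.07) and Pmaip1 (-1.09, SE 0.06) and the p53 antagonist Mdm2 (-0.59, SE 0.03) fell, and the antiproliferative Btg2 (0.23, SE 0.04) rose. Macrophage and stellate cell markers, given among the other cell types, fell in the same libraries as all 3 of these lists.

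**Figure D3:**
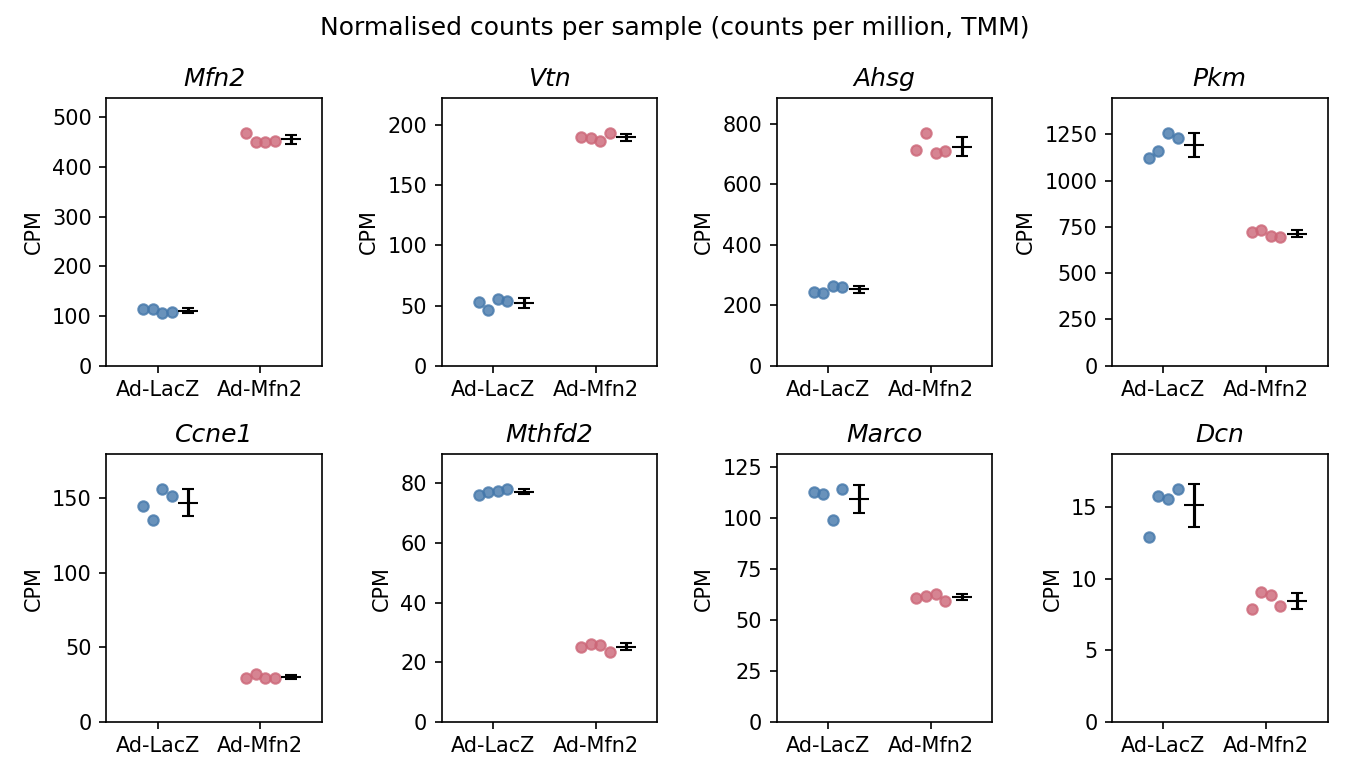
Normalised counts per sample (CPM, linear axes from 0) of 8 genes in the 4 Ad-LacZ and 4 Ad-Mfn2 samples, 1 point per sample with the group mean ± SD beside them. The groups do not overlap for any of the 8, and Mfn2 stands at 111 CPM against 455 CPM.

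Genes of mitochondria moved in both directions. In the fusion and fission list, 7 of 20 tested members were higher, 7 lower and 6 not called (camera adjusted p = 0.744). Mfn2 itself is 1 of the higher, and without it 6 of 19 were higher, 7 lower and 6 not called (adjusted p = 0.985). Mfn1, the other mitofusin, was slightly higher (0.17, SE 0.05, adjusted p = 0.00423), and Opa1, the inner membrane fusion GTPase, was slightly lower (-0.19, SE 0.05, adjusted p = 0.00166). The fission GTPase Dnm1l was not called (0.010, SE 0.05, adjusted p = 0.880), turned negative (-0.087) without Ad-LacZ replicates 3 and 4 and was called (0.12) without 1 and 2. The inner membrane protease Oma1 (0.44, SE 0.07) rose and Mtfr1 (-0.32, SE 0.04) fell. The differences of Mfn1, Opa1 and Mtfr1 did not pass the test against 1.2-fold. Complex I genes had 15 higher, 2 lower and 20 not called of 37 (camera adjusted p = 0.0685), with Ndufc1 (0.82, SE 0.06) higher and Ndufb3 (-0.21, SE 0.06) lower, the latter not without Ad-LacZ replicates 3 and 4 (adjusted p = 0.0725). Without Ad-LacZ replicate 3 (adjusted p = 0.0111) or Ad-Mfn2 replicate 11 (0.0344) this list was called as higher, as it was without the filter on low counts (0.0169). Complexes II to V had 11 higher, 9 lower and 21 not called of 41 (11 higher and 7 lower adjusted over the list alone, adjusted p = 0.464). Without Ad-LacZ replicates 3 and 4 complexes II to V were called as higher (median 0.11, adjusted p = 0.0365), and without 1 and 2 their median was -0.032 (adjusted p = 0.635). The mitochondrial ribosome had 12 higher, 29 lower and 35 not called of 76 (11 higher and 29 lower adjusted over the list alone, adjusted p = 0.0956), with Mrpl39 (-0.48, SE 0.05) lower and Mrpl24 (0.49, SE 0.05) higher. It was called as lower without Ad-LacZ replicate 2 (adjusted p = 0.0287).

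Mitochondrial biogenesis had 2 higher, 7 lower and 9 not called of 18 (camera adjusted p = 0.199), with the mitochondrial DNA packaging factor Tfam (-0.48, SE 0.05) lower and the mitochondrial RNA polymerase Polrmt (0.26, SE 0.07) higher. The Polrmt call ended with GC trends removed (adjusted p = 0.0830). The tricarboxylic acid cycle had 6 higher, 6 lower and 10 not called of 22 (adjusted p = 0.884), its median (0.049) and mean (-0.0071) differing in sign. Phospholipid synthesis and contacts between endoplasmic reticulum and mitochondria had 13 higher, 9 lower and 13 not called of 35 (adjusted p = 0.525). Mitochondrial chaperones and proteases were lower as a list, 2 higher, 14 lower and 9 not called of 25, median -0.17 (camera adjusted p = 0.0330, and adjusted p = 0.529 with an estimated correlation). They included Hspa9 (-0.65, SE 0.03), Hspd1 (-0.47, SE 0.04) and Lonp1 (-0.53, SE 0.04), with the protease Htra2 (0.43, SE 0.06) higher. That call ended without Ad-LacZ replicate 4 (adjusted p = 0.0556) or Ad-Mfn2 replicate 9 (0.0653). Autophagy and mitophagy genes were higher as a list, 14 higher, 4 lower and 13 not called of 31, median 0.11 (camera adjusted p = 0.0303, and adjusted p = 0.297 with an estimated correlation). Among them were Map1lc3a (0.76, SE 0.05), Calcoco1 (0.65, SE 0.05) and Ulk1 (0.58, SE 0.05), with the mitophagy receptor Bnip3 (-0.31, SE 0.05) lower. Their call ended without Ad-LacZ replicate 2 (adjusted p = 0.0552) or Ad-Mfn2 replicate 10 (0.0539). Macrophage and stellate cell markers fell in the same libraries as the chaperone and autophagy lists were called (medians -0.42 and -0.49, the latter -0.28 at 10 CPM or more). Genes encoded in mitochondrial DNA were not analysed here.

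The unfolded protein response, antioxidant, interferon, NF-kB, ribosome, proteasome and actin lists were not called by camera. The unfolded protein response of the endoplasmic reticulum had 7 higher, 17 lower and 5 not called of 29 (7 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.0956), with its transcription factor Xbp1 (0.51, SE 0.04) higher and Herpud1 (-0.47, SE 0.05) lower. NRF2 and antioxidant genes had 14 higher, 13 lower and 7 not called of 34 (15 higher and 13 lower adjusted over the list alone, adjusted p = 0.621), with Gstm1 (0.97, SE 0.03) higher, whose reads can be shared with other Gstm genes, and haem oxygenase (Hmox1, -1.14, SE 0.04) lower. The type I interferon response had 14 higher, 6 lower and 15 not called of 35 (14 higher and 5 lower adjusted over the list alone, adjusted p = 0.206), with Irf7 (0.51, SE 0.06) higher and Cmpk2 (-0.40, SE 0.06) lower. NF-kB and cytokine genes had 11 higher, 11 lower and 5 not called of 27 (12 higher and 11 lower adjusted over the list alone, adjusted p = 0.884), with the chemokine Ccl2 (0.68, SE 0.04) higher and the adhesion molecule Vcam1 (-0.66, SE 0.04) lower. Cytosolic ribosomal proteins had 16 higher, 18 lower and 46 not called of 80 (16 higher and 16 lower adjusted over the list alone, adjusted p = 0.919) and the proteasome 6 higher, 16 lower and 21 not called of 43 (adjusted p = 0.201). Without Ad-LacZ replicates 3 and 4 the cytosolic ribosome was called as higher (median 0.075, adjusted p = 0.0329). Without 1 and 2 its median was -0.075 (adjusted p = 0.0556), and the proteasome was called as lower (-0.10, adjusted p = 0.0269). Actin, YAP and dedifferentiation genes had 11 higher, 12 lower and 7 not called of 30 (11 higher and 13 lower adjusted over the list alone, adjusted p = 0.941), their median (0.024) and mean (-0.021) differing in sign. In that list alpha-fetoprotein (Afp, 1.25, SE 0.05) was higher and the tubulin Tubb6 (-0.74, SE 0.04) lower.

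Markers of 2 other liver cell types were called lower by camera. For Kupffer cells and macrophages, 0 of 17 tested members were higher, 12 lower and 5 not called, median -0.42 (camera adjusted p = 0.00348, and adjusted p = 0.133 with an estimated correlation). The scavenger receptor Marco was measured at 109 ± 7.02 CPM in Ad-LacZ and 61.1 ± 1.42 CPM in Ad-Mfn2 (-0.84, SE 0.05), and Cd5l (-0.91, SE 0.05) and Lyz2 (-0.48, SE 0.04) fell with it. For stellate cells and fibroblasts, 1 of 14 tested members were higher, 12 lower and 1 not called, median -0.49 (camera adjusted p = 0.00191, and adjusted p = 0.0701 with an estimated correlation). The median of the 9 with at least 10 CPM was -0.28, 7 of them lower and 1 higher. The proteoglycan gene Dcn (-0.84, SE 0.09) and Tagln (-0.46, SE 0.05), which the actin list also holds, fell. Fbln2 (0.10, SE 0.04) was slightly higher, a call that ended with GC trends removed and without Ad-LacZ replicate 1, Ad-Mfn2 replicate 9 or Ad-Mfn2 replicate 11 (adjusted p = 0.0792, 0.0998 and 0.0566). Endothelial markers were not called as a list by camera, 2 higher, 5 lower and 7 not called of 14 (median -0.34, camera adjusted p = 0.213). Fry, which does not compare them with other genes, called them lower (fry adjusted p = 0.0275). The lymphatic and sinusoidal marker Lyve1 (-0.65, SE 0.15) fell, and Cdh5 was not called (-0.12, SE 0.12, adjusted p = 0.396). Without Ad-LacZ replicates 3 and 4 Cdh5 was called (-0.32), and without 1 and 2 it turned positive (0.13). Stab1 (0.20, SE 0.07) was slightly higher, but not with length or GC trends removed or without Ad-LacZ replicate 4 (adjusted p = 0.0512). Cholangiocyte markers, 4 of which are also in the actin list, had 5 higher, 2 lower and 5 not called of 12 (adjusted p = 0.333), with Pkhd1 (0.98, SE 0.06), Spp1 (0.58, SE 0.03) and Krt19 (0.16, SE 0.04) higher and Tspan8 (-0.64, SE 0.08) lower. The Krt19 call ended with GC trends removed (adjusted p = 0.150). No lymphocyte or granulocyte marker had over 7 counts in any library, and of the red cell genes Alas2 alone could be tested (-0.46, SE 0.28, adjusted p = 0.178).

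Gene calls came from edgeR's quasi-likelihood test and list calls from camera, both with Benjamini-Hochberg adjustment. For 25 of the 35 lists the counts adjusted over the list alone equalled those over all genes tested, and the other 10 have both counts beside them. Beyond Mfn1, Opa1 and Mtfr1, the small differences of Por, Hadha, Cpt1a, Btg2, Bnip3, Fbln2, Stab1, Krt19, Ndufb3 and Polrmt did not pass the test against 1.2-fold. No uninfected sample and no viral transcript was analysed here, so the dose of the 2 viruses was not compared. For the same reason, genes said to rise or fall did so relative to the control virus, whose own effect was not measured.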

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

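In this part, the tests of cell shares, of cell cycle genes against other cell types and of virus dose were chosen only after the result was seen, as were the removal of length and GC trends as a setting and the bounds of the cell share tests, with their use of markers of at least 10 CPM. The tRNA synthetase lists were written after the ATF4 result and before their own values were seen, and Foxa2, Clec4f and the synthetase genes were named after their values were seen. 13 of 324 groups of 4 samples held a sample far from the other 3, where chance, at about 1 in 20 groups, gives 16.2. Within Ad-Mfn2 these were 468 CPM for Mfn2 in replicate 9 (others 449.8 to 452), 32.2 CPM for Ccne1 in replicate 10 (others 29.2 to 29.4), 82.9 CPM for Mtfr1 in replicate 9 (others 91.1 to 92.3), 769.8 CPM for Ahsg in replicate 10 (others 704 to 713), 16.1 CPM for Mvk in replicate 10 (others 14.3 to 14.5), 72.3 CPM for Ulk1 in replicate 10 (others 78.9 to 80.2), 275 CPM for Aars in replicate 10 (others 258 to 260.3) and 795 CPM for C4b in replicate 9 (others 768 to 771). Within Ad-LacZ they were 99.0 CPM for Marco in replicate 3 (others 112 to 114), 39.7 CPM for Cmpk2 in replicate 3 (others 34.9 to 35.5) and 104 CPM for Got1 in replicate 1 (others 99.8 to 100.4). The mean log2 CPM of acute phase proteins was 6.61 in Ad-LacZ replicate 2 (others 6.70 to 6.72). The mean log2 CPM of bile acid synthesis and transport was 4.46 in Ad-Mfn2 replicate 9 (others 4.49 to 4.50).

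Of the 35 ways to split the 8 samples into 4 and 4, only 1, the real one, gave as many as 8167 changed genes in edgeR. The highest of the others gave 0, but every other split mixes the 2 groups, which widens the spread within each set. The real split ranked 1 of 35, the best rank that 4 against 4 samples allow. Chance in how these 8 samples fell into groups is thus unlikely but not excluded. A chance difference between 2 cultures is not excluded if the samples of a group are repeats of 1 culture, and any handling that went with a group is not separated from the virus by this design.

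Hepatocyte genes were higher while macrophage and stellate markers were lower, and a smaller share of other cells in the Ad-Mfn2 samples is a candidate explanation. Such a change raises every hepatocyte gene by a common factor, but the SD of the members' log2 fold changes was 9.84 times their median SE, from -0.14 for Foxa2 to 1.87 for Vtn, which argues against it as the whole cause. A common factor for macrophages also met a wide spread (ratio 3.67), with Cd5l at -0.91 and Clec4f, not called, at 0.21, and Lyz2, the most abundant, at 200.2 CPM in Ad-LacZ. For stellate markers the ratio was 2.98 over all 14, within its bound of 3, and 4.07 over the 9 of at least 10 CPM, whose median was -0.28 against -0.49. A chi-square test found the members unequal in both sets, and the most abundant, Fbln2 (209.6 CPM in Ad-LacZ), was not lower. These values argue against a common factor for all stellate markers as the whole cause. They bear on the share of a cell type only if that cell type alone expresses its markers, which was not tested. The SEs used in these comparisons measure only the spread between these samples, which can be technical. Removing each library's trends with transcript length and GC content left the hepatocyte median at 0.75, from 0.72 before (camera adjusted p = 3.26e-11). These trends are thus not the whole cause. Fewer other cells combined with altered expression, an effect of Mfn2 itself and an effect of the control virus stay open.

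Cell cycle genes were lower, 33 of 34, and fewer dividing non-hepatocyte cells could contribute. Their median of -0.64 lay below the -0.39 of 45 macrophage, stellate and endothelial markers (permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give) and below the -0.49 of stellate markers alone (p = 0.0359). With markers of at least 10 CPM these medians were -0.35 (permutation test over genes, p = 1e-05) and -0.28 (p = 0.00237). Genes are not independent replicates. If these cells alone express their markers, which was not tested, this argues against a loss at the median rate of the markers. Macrophage markers alone ran from -0.91 for Cd5l to 0.21 for Clec4f, not called. A loss larger than the median is therefore not excluded. With length and GC trends removed the median was -0.63 (camera adjusted p = 2.39e-13), so those trends are not the whole cause. A different dose of the 2 viruses cannot be told apart from an effect of Mfn2. Viral transcripts were not analysed here, no uninfected group was used here, and the interferon list gave no call (camera adjusted p = 0.206). Without an uninfected group, a rise of these genes caused by Ad-LacZ cannot be told apart from a fall caused by Ad-Mfn2 either.

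ATF4 genes were lower, with a median of -0.76 and, after removal of length and GC trends, -0.82 (camera adjusted p = 1.47e-09), which argues against these trends as the whole cause. The biological hypothesis that ATF4 activity was lower predicts a fall of cytosolic but not mitochondrial aminoacyl-tRNA synthetase genes, which no fixed list held. Of the cytosolic set 16 of 20 were lower and 0 higher (median -0.38, camera adjusted p = 3.57e-06, and adjusted p = 0.0139 with an estimated correlation), with Cars (-0.91, SE 0.04), Rars (-0.86, SE 0.04) and Aars (-0.59, SE 0.03), while of the mitochondrial set 8 of 17 were higher and 1 lower (median 0.15, camera adjusted p = 0.0865), with Vars2 (0.75, SE 0.06) and Iars2 (0.26, SE 0.04). The medians differed as the hypothesis predicts (permutation test over genes, p = 1e-05, the smallest the permutations can give), although genes are not independent replicates. Other causes of a fall in cytosolic synthetase genes were not tested, so the contrast does not single out ATF4. Macrophage and stellate markers fell in the same libraries (medians -0.42 and -0.49, the latter -0.28 for those of at least 10 CPM). Protein and translation were not analysed here, and virus dose and an effect of the control virus stay open here as well.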

How the results depend on the processing

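In this part, the test against 1.2-fold, the removal of length or GC trends, the thinning of libraries and the removal of Ad-LacZ replicates 3 and 4 or 1 and 2, or of Ad-Mfn2 replicates 9 and 11 or 10 and 12, and of Mfn2 from the fusion and fission list, were chosen only after the result was seen. No paired analysis was possible because the groups share no replicate numbers. Without the filter on low counts, 1060 genes changed at least 2-fold against 682, as more genes of few counts were tested. Against 1.2-fold, 3755 genes passed, 1837 higher and 1918 lower, since that test asks for a larger change. List calls numbered 2 with an estimated correlation and 26 with fry. Those that fry added were fusion and fission, complex I, biogenesis, lipogenesis, phospholipid synthesis, gluconeogenesis, unfolded protein response, insulin signalling, endothelial and cholangiocyte markers. The fusion and fission list holds Mfn2, the delivered gene, and fry was not run without it. That fry call therefore does not speak for the other members of the list. Dnm1l, not called, turned to -0.087 without Ad-LacZ replicates 3 and 4 and to -0.011 without Ad-Mfn2 replicates 10 and 12, and ran from -0.026 to 0.063 when each replicate was left out, below 0 without Ad-LacZ 3 (-0.019), Ad-LacZ 4 or Ad-Mfn2 12 (-0.00078). It was called at 0.12 without Ad-LacZ replicates 1 and 2. Cdh5 turned to 0.13 without Ad-LacZ replicates 1 and 2 and was called at -0.32 without replicates 3 and 4, and the cause was not tested. With 1 replicate left out, 7677 to 8156 genes changed (3822 to 4107 higher, 3855 to 4049 lower), 684 to 731 reached 2-fold, Mfn2 stayed at 2.02 to 2.06 and 15 to 17 lists were called. Under the other settings, apart from the 1.2-fold test, 7007 (without Ad-Mfn2 replicates 10 and 12) to 8698 (length and GC trends removed) genes changed, and 48.9 to 51.3% of calls were higher genes. Each scaling used centres the fold changes on the bulk of genes, with medians over all genes of -0.037 to 0.011. That share therefore cannot test whether the response was balanced. DESeq2 list tests were not run, and the alternatives for normalized values did not apply to counts. Of the values of named genes, 2944 kept direction and call, 38 lost the call, 10 gained it and 6 turned. Foxa2 was called lower with the 1 CPM filter (-0.15), with length, GC or both trends removed (-0.14, -0.22 and -0.22) and without Ad-LacZ 4, Ad-Mfn2 9, Ad-LacZ 3 and 4 or Ad-Mfn2 9 and 11 (-0.16, -0.17, -0.18 and -0.20). Calls lost against 1.2-fold were those of Bnip3, Btg2, Cpt1a, Fbln2, Hadha, Iars2, Krt19, Mfn1, Mtfr1, Ndufb3, Opa1, Polrmt, Por and Stab1. With GC trends removed, the calls of Fbln2 (0.017), Stab1 (0.11), Krt19 (0.062) and Polrmt (0.12) ended, and Ndufb3 lost its call without Ad-LacZ replicates 3 and 4. Without Ad-LacZ replicates 1 and 2 the PPAR-alpha, cholesterol and autophagy list calls ended (adjusted p = 0.0620, 0.0516 and 0.0866). The call of mitochondrial chaperones ended without replicates 3 and 4 (0.0874). Complex I (0.17), complexes II to V (0.11) and the cytosolic ribosome (0.075) were called as higher there, where without replicates 1 and 2 the medians of the latter pair were -0.032 and -0.075, not called. The mitochondrial ribosome (-0.14) and proteasome (-0.10) were called as lower without replicates 1 and 2. Without Ad-Mfn2 replicates 9 and 11 complex I was called as higher (0.13), and the calls of mitochondrial chaperones (adjusted p = 0.115), Hadha, Fbln2, Stab1, Krt19 and Polrmt ended. Without 10 and 12 the mitochondrial ribosome was called as lower (-0.10), and the autophagy (adjusted p = 0.0650) and Hadha calls ended. Length trends removed also gave the mitochondrial ribosome, and no filter gave complex I, lipogenesis and gluconeogenesis (0.39 against 0.11). Medians or test directions of the cytosolic ribosome, complexes II to V, tricarboxylic acid cycle, NF-kB and actin lists changed sign under some settings, as did the test direction of the fusion and fission list without Mfn2 (median 0.019 against 0.049, adjusted p = 0.985). The other 12 list calls were lost under no setting run except an estimated correlation. The cell cycle and ATF4 calls were kept there too.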

Other observations

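In this part, the heat shock, complement and lobule zone lists and their tests were chosen only after the result was seen, and the genes named from them were chosen after their values were seen. Complement and coagulation genes, held in no fixed list, rose as well. Of 35 complement and coagulation genes, 30 were higher, 1 lower and 4 not called, with a median log2 fold change of 0.54 (camera adjusted p = 2.34e-10, and adjusted p = 0.0139 with an estimated correlation). They included the plasmin inhibitor gene Serpinf2 (1.43, SE 0.05), kininogen (Kng1, 1.01, SE 0.04), complement factor B (Cfb, 0.81, SE 0.03) and C4b (0.74, SE 0.03), while of the mannose-binding lectin genes Mbl1 (1.41, SE 0.13) rose and Mbl2 (-0.55, SE 0.05) fell. In the same libraries macrophage and stellate markers fell (medians -0.42 and -0.49, the latter -0.28 for those of at least 10 CPM). A hypothesis is that the rise of secreted liver proteins is broader than the fixed lists, which a list written after that rise was seen cannot decide, so it stays open.

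Cytosolic heat shock chaperones were lower, 22 of 28 with 4 higher and 2 not called, median -0.23 (camera adjusted p = 2.11e-04, and adjusted p = 0.155 with an estimated correlation). Hspa1a, which can share reads with Hspa1b, had the largest fall (-3.89, SE 0.17), and Hsp90aa1 (-0.69, SE 0.03) and Hsph1 (-0.53, SE 0.03) fell less, while their transcription factor gene Hsf1 (0.53, SE 0.06) was higher. A hypothesis is a coordinated fall of these chaperones. The list was written after the fall of Hspa1b was seen and holds Hspa1b and Hspa1a, so its test decides nothing and this stays open. Macrophage and stellate markers, with the medians given above, fell in the same libraries.

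Hepatocyte genes could have risen in 1 zone of the liver lobule only, which predicts different medians for genes of cells near the central vein and near the portal tract. The 15 pericentral genes, 4 of them also in fixed lists, had 9 higher, 2 lower and 4 not called, and the 17 periportal genes, 9 also in fixed lists, 10 higher, 3 lower and 4 not called (camera adjusted p = 0.0213 for each list, and adjusted p = 0.155 with an estimated correlation). Their medians were 0.23 and 0.28, a difference of -0.048 with a 95% bootstrap interval over genes of -0.50 to 0.39 (permutation test over genes, p = 0.650). The interval is wide against the effect of interest, so a shift of zone stays open.

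A predicted gene listed as Gm5643_1, singled out after its values were seen, had 190, 941, 908 and 47 counts in Ad-LacZ replicates 1 to 4 and 0 to 8 counts in the Ad-Mfn2 samples. Rnaset2a and Rnaset2b, near-identical genes that can share reads and were singled out in the same way, moved in opposite directions, Rnaset2a from 2716 to 2990 counts in Ad-LacZ to 1777 to 2181 in Ad-Mfn2 and Rnaset2b from 135 to 264 to 350 to 607, not scaled for depth.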
